A study of Saccharomyces cerevisiae with 51 samples.

How the data were processed

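The series comprises 51 chromatin immunoprecipitation sequencing (ChIP-seq) libraries from budding yeast of the BY4741 background. Libraries were made from input DNA, from chromatin immunoprecipitated for histone H3 and from chromatin immunoprecipitated for histone H3 phosphorylated at serine 10 (H3pS10). Reads were aligned with Bowtie2 version 2.2.9, per the submitters' processing notes. The genome build and any later step from alignments to values are not given in the sources used here.

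The 6 files analysed here hold no value for any library. They describe the genome in a version called before and a version called after, and each version has a table of chromosome lengths, a grid of bins and a gene annotation. The authors' deposited bins are start and end positions in bp on each chromosome, with no score or other value attached. The deposited annotations are lists of exon, coding, codon and transcript records whose source field names Ensembl, and they too carry no score. Because there are no reads or signals in these files, the depth of the libraries is unknown. No coverage, interval or detection limit was computed. No file header or label says which libraries were aligned to which version.

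Libraries were assigned to groups from their descriptions. The tests planned before the data were examined for H3pS10 over H3, with and without estradiol, needed a value per library and were not run. The coordinate comparisons planned for the same files were made instead. Chromosome lengths were compared between the length tables. Genes were matched by identifier, and a gene's extent ran from the first to the last base of all its records. A change in the shift of gene coordinates along a chromosome defined a changed interval, bounded by the nearest annotated genes. Bins were numbered from 1 along each chromosome. Same-numbered bins of both grids were compared for overlap in the coordinates as deposited and for the sequence they share, after the right-side coordinates of the after version had been moved back by the shift of the genes. Bases of the changed interval were left out of the shared sequence, since the breakpoints inside it cannot be placed from gene coordinates. A gene was placed in the bin that held its midpoint. All coordinates are 1-based positions in the version named.

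Chromosome arms were read from the systematic gene identifiers, in which the third letter gives the left or right arm. The interval between the arms ran, by coordinate, from the end of the last left-arm gene to the start of the first right-arm gene. Gene identifiers were also looked up in the NCBI gene table of assembly R64, which was used for names and gene order only. Of 7126 identifiers, 6048 matched a locus tag. The 10 gene lists used (59 genes: chromosomal passenger complex; shugoshin, Bub1 and PP2A; condensin; cohesin; histones; sirtuins and silencing; mitotic exit; spindle checkpoint; PP1; kinetochore CBF3 and CENP-A loading) were fixed before the data were examined. NDC10 was matched through that table to CBF2, its name in the annotation. The rule for named genes, also fixed beforehand, took genes present in 1 annotation only, genes with another length or strand, the 5 genes nearest each side of a changed interval, list members on a chromosome of changed length, and the genes mutated or fused in the strains.

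The coordinate comparisons are exact differences between text files. They have no replicates and no sampling error, and no test was applied to them. The comparison was tested on simulated data: 50 deletions of random size were put between genes of the 7071 nuclear genes, and the place and size of all 50 were recovered. The place here is the interval between the flanking genes, not the breakpoints inside it. No insertions were simulated, so this checks only the arithmetic of the comparison. The alternatives were other sources of chromosome length, other definitions of a gene's extent, matching by gene name, stricter overlaps of 50% and 90%, and other ways to place a gene in a bin. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 were used.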

Results

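The libraries covered 7 strains in 13 combinations of strain and treatment, each with input DNA, an H3 ChIP and an H3pS10 ChIP, 17 libraries of each kind. H3pS10 is a mitotic histone mark placed by the Aurora B kinase, which is Ipl1 in budding yeast. Wild-type cells were sampled in 3 numbered replicates with beta-estradiol (E2, 1 nM for 3 hours) and 3 without. Single libraries per assay, with and without E2, came from 4 altered strains. One carried an Ipl1 fusion, described as ipl1-TetR-mCh, and another a fusion of Sgo1, described as sgo1-TetR-mCh. Sgo1 is the shugoshin protein of the pericentromere. The third lacked SGO1, and the fourth had the H3-S10A histone, in which serine 10 is replaced by alanine. Single libraries per assay also came from wild-type, ipl1-321 and cdc15-1 cells held at 37 °C for 90 minutes. The ipl1-321 allele is a temperature-sensitive form of the Aurora B gene, and Cdc15 is a kinase of the mitotic exit network. In all, 21 libraries were labelled with E2, 21 with neither treatment and 9 as heat treated.

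The design asks how centromeres bear on the condensation of chromosome arms in mitosis, read through H3pS10 relative to H3 in wild-type and altered cells. The comparisons of H3pS10 between E2 and untreated cells, between strains, and between heat-treated wild-type, ipl1-321 and cdc15-1 cells were not analysed here, because the files used hold coordinates and no signal. Of 39 groups, 33 had 1 library and 6, all wild type, had 3. The files answer a narrower question, namely how the genome changed between the before and after versions and which genes and bins the change touched.

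Only chromosome IV, the longest of the 17 chromosomes, differed in length between the versions. It measured 1535038 bp before and 1531615 bp after, a difference of -3423 bp or -0.22% of its length. The other 16 chromosomes, the mitochondrial one included, had equal lengths in both. The whole genome went from 12160210 to 12156787 bp.

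The difference lay in a single stretch of chromosome IV between the neighbouring genes RMD1 (YDL001W) and NTH1 (YDR001C), the gene for neutral trehalase. This stretch ran from 449277 to 453324 in the before version, 4048 bp, and from 449277 to 449901 in the after version, 625 bp. RMD1 is the last gene of the left arm and NTH1 the first gene of the right arm by their systematic names, and the centromere of a yeast chromosome lies between its arms. RMD1 is on the plus strand and NTH1 on the minus strand, so the 3′ ends of both faced the interval. The same genes are neighbours in the R64 gene order. No exon, coding, codon or transcript record fell inside the interval in either version. This was fixed in advance, because the interval is bounded by the nearest annotated genes, so it says nothing about the sequence inside.

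Between the annotations, no gene was gained, lost, resized or turned around. The annotations also list genes that BY4741 cells lack, so they cannot show which genes the cells carry, inside the interval or elsewhere. Both annotations held 7126 genes in 34945 records. All 6240 genes of the other chromosomes kept their coordinates. On chromosome IV, 268 of 886 genes kept theirs and 618 genes (69.8%) moved by -3423 bp. The 618 were 591 protein-coding genes, 23 tRNA genes, 3 snoRNA genes and 1 pseudogene. The 268 were 262 protein-coding genes, 5 tRNA genes and 1 snoRNA gene. None of the 262 genes with a left-arm name moved, and all 592 with a right-arm name did.

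The genes nearest the interval kept their order and spacing within each side. On the left, MED2 (YDL005C, 441014 to 442309), a Mediator subunit, ATP16 (YDL004W, 443029 to 443511), the delta subunit of mitochondrial ATP synthase, MCD1 (YDL003W, 444683 to 446383), the kleisin subunit of cohesin, NHP10 (YDL002C, 446967 to 447578), an INO80 remodeller subunit, and RMD1 (447984 to 449276) had the same positions in both versions. On the right, NTH1 went from 453325 to 449902 at its lowest coordinate, which is given for each gene here. YRB1 (YDR002W), which encodes a Ran-binding protein, went from 456150 to 452727. RCR2 (YDR003W) went from 457227 to 453804, YDR003W-A from 457887 to 454464, and RAD57 (YDR004W), a recombinational repair gene, from 458306 to 454883.

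**Figure D1:**
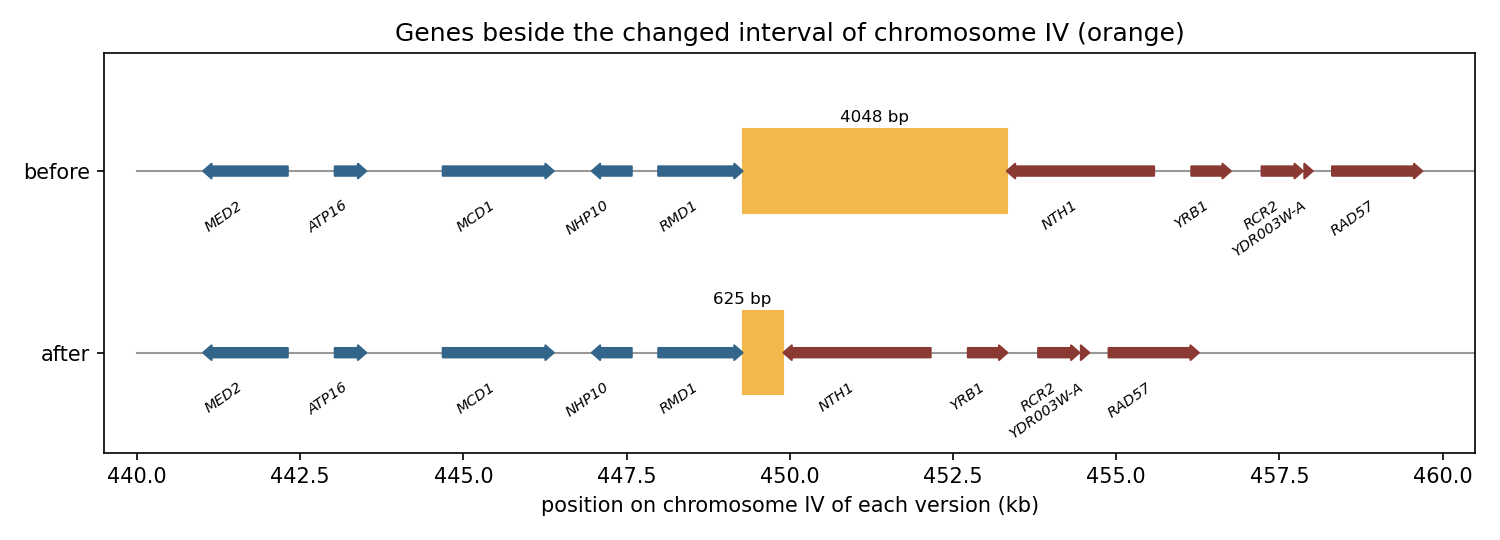
Map, to scale, of the 5 genes on each side of the changed interval in the before (upper) and after (lower) versions of chromosome IV, with position in kb on the horizontal axis, arrows for genes and their direction, and the interval in orange. The left genes (blue) keep their positions, and the right genes (red) lie 3423 bp further left after, with the interval at 4048 bp before and 625 bp after.

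The interval between the arms of chromosome IV was longer before, and shorter after, than that of any other nuclear chromosome. The intervals of the other 15 chromosomes ranged from 630 bp on chromosome VII, between ERG26 and AML1, to 2541 bp on chromosome V, between IRC22 and MNN1, with a median of 1005 bp. Before, the interval was also the longest of the 790 stretches between neighbouring genes on chromosome IV, whose median was 355.5 bp (355.5 bp after as well). After, 159 of these stretches were longer. The right arm, measured from the lowest coordinate of NTH1 to the chromosome end, was 1081714 bp in both versions and the longest of the 32 arms. The left arm, up to the last base of RMD1, was 449276 bp in both.

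**Figure D2:**
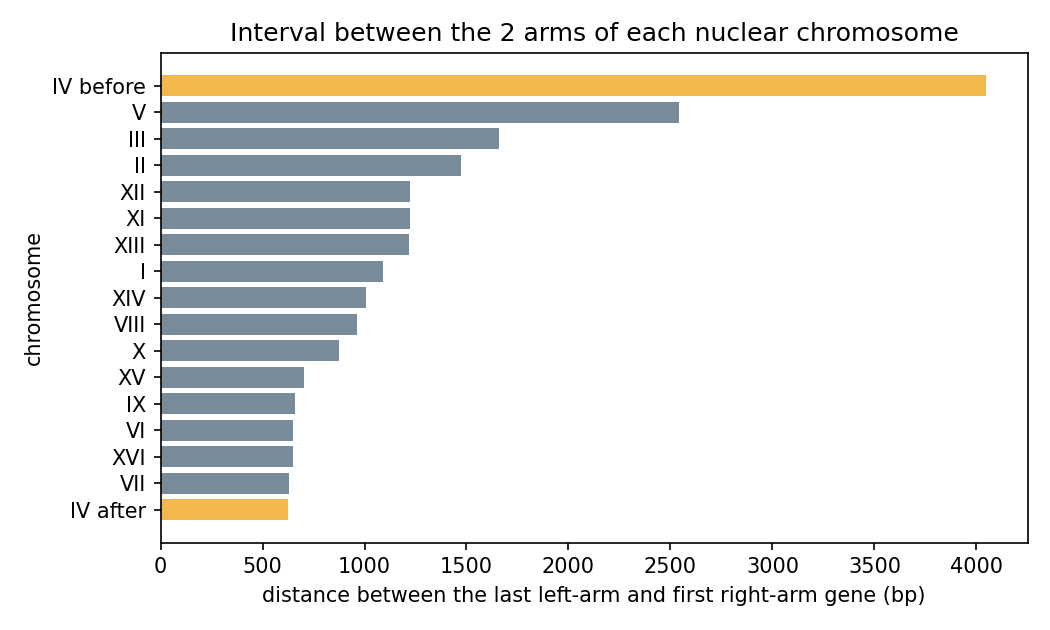
Bars give, in bp from 0, the distance between the last left-arm and the first right-arm gene of each nuclear chromosome, with chromosome IV drawn once for each version (orange). Chromosome IV has the longest bar before (4048 bp) and the shortest after (625 bp), and the other 15 chromosomes lie between 630 and 2541 bp.

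Among genes of the mitotic chromosome machinery, 13 of 59 list members lay on chromosome IV, against 886 of all 7126 genes. Of the 13 members, 7 moved and 6 did not, and of the 886 genes 618 (69.8%) moved. Whether a member moved followed from its arm alone, so the moves below are coordinate offsets and say nothing about gene function. Both histone members on this chromosome moved. At the lowest coordinate of each gene, HTA1 (YDR225W), an H2A gene, went from 918635 to 915212. HTB1 (YDR224C), an H2B gene, went from 917422 to 913999. The 1 condensin member, YCG1 (YDR325W), went from 1120231 to 1116808. Of the 3 cohesin members, RAD61 (YDR014W) went from 477151 to 473728 and the loader gene SCC2 (YDR180W) from 824400 to 820977, and MCD1 kept its place. SIR4 (YDR227W), a silencing gene, went from 920676 to 917253, and SKP1 (YDR328C), a CBF3 subunit gene, from 1128539 to 1125116.

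The members that kept their coordinates were all on the left arm. They were, beside MCD1, the sirtuin gene SIR2 (YDL042C, 376757 to 378445), the checkpoint kinase gene MPS1 (YDL028C, 400997 to 403291), the PP2A catalytic genes PPH21 (YDL134C, 219662 to 220771) and PPH22 (YDL188C, 123865 to 124998), and SCM3 (YDL139C, 211375 to 212046), which encodes the chaperone of the centromeric histone. No member of the chromosomal passenger complex, mitotic exit or PP1 lists lay on chromosome IV. The genes altered in the strains, and the H3 genes, lay elsewhere and had equal coordinates in both versions: IPL1 on chromosome XVI (156490 to 157593), SGO1 on chromosome XV (464771 to 466543), CDC15 on chromosome I (172211 to 175135), HHT1 on chromosome II (256331 to 256741) and HHT2 on chromosome XIV (575640 to 576050).

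Each nuclear chromosome was divided into 500 bins and the mitochondrial one into 499, so the bins followed chromosome length. They were 461 bp wide on chromosome I and 3071 bp on chromosome IV in the before grid, a 6.66-fold range. With 886 genes, chromosome IV had 1.77 genes per bin, against 0.254 on chromosome I. Of 8499 bins, 7999 had the same coordinates in both grids. The 500 that differed were those of chromosome IV. Except for the last, they were 3064 bp wide after, 7 bp (0.23%) narrower than before. The last bin measured 2609 bp before and 2679 bp after. The changed interval spanned bins 147 and 148 before and lay within bin 147 after. The difference of 3423 bp corresponds to 1.11 bins of the before grid.

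Same-numbered bins of chromosome IV did not hold the same sequence in both grids. To the left of the interval, in bins 1 to 146, the after bins started up to 1015 bp to the left of their before counterparts, and the sequence shared fell from 99.8% to 66.7% toward the interval. To the right, bin 149 started 2387 bp further right in the sequence and shared 22.3%, and the shared part grew to 99.8% near the right end. Bins 147 and 148 shared 29.6% and 22.0%. The value of bin 147 is a lower bound, because it held bases of the changed interval in both grids and these were left out. In all, 376 of 500 bin pairs shared 50% or more of their sequence and 97 shared 90% or more.

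**Figure D3:**
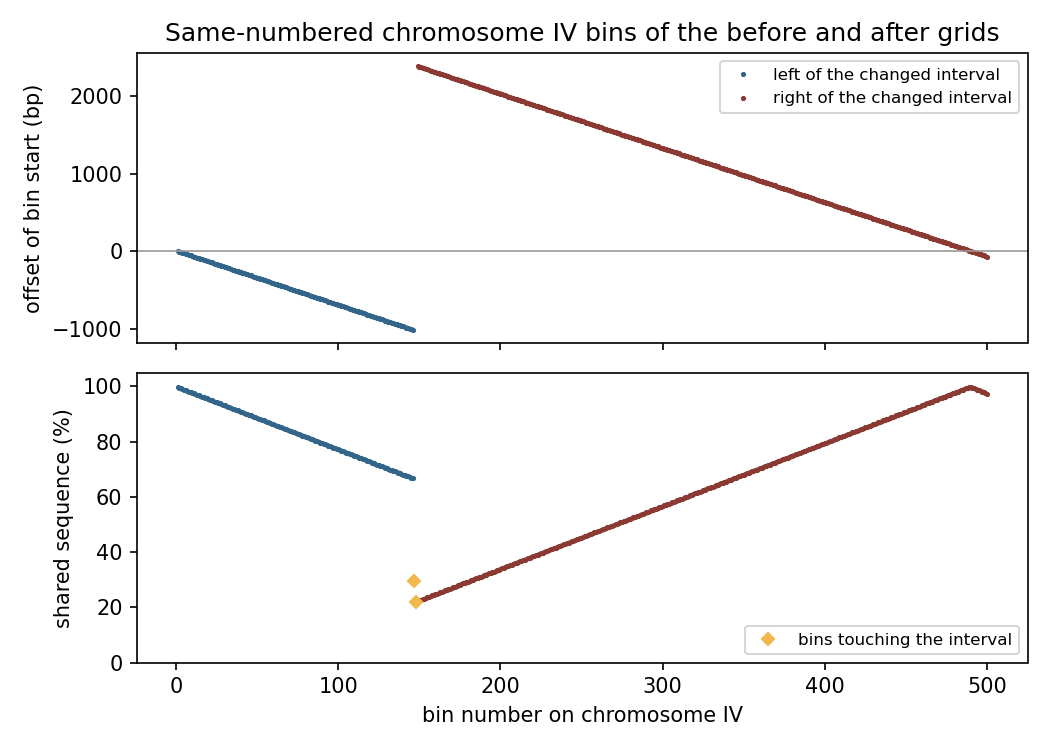
Same-numbered chromosome IV bins of both grids by bin number, with the offset in bp of the after bin's start along the sequence (upper) and the percent of sequence shared (lower), for bins left (blue) and right (red) of the changed interval and for the 2 that touch it (orange, lower panel). The offset reaches -1015 bp on the left and 2387 bp on the right, and the shared sequence is lowest in bin 148, at 22.0%, followed by bin 149, at 22.3%.

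As a result, 280 of 886 genes on chromosome IV (31.6%) had another bin number in the after grid. Of the 268 left-side genes, 51 fell 1 bin higher, among them SIR2 (bin 123 before, 124 after), MPS1 (131 and 132) and SCM3 (69 and 70). Of the 618 right-side genes, 229 fell 1 bin lower, among them RAD61 (156 and 155), SCC2 (270 and 269) and HTA1 (300 and 299). HTB1, the neighbour of HTA1, was in bin 299 in both, so this divergent H2A and H2B gene pair was split over 2 bins before and shared 1 after. MCD1 (bin 146), YCG1 (bin 366), SIR4 (bin 301) and SKP1 (bin 368) kept their bin number.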

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

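The length difference of chromosome IV was -3423 bp from the length tables, the last bins and the last annotated features alike. These are not independent checks, because the last bins end at the tabulated lengths and the last features lie among the moved genes. The count of moved genes was 618 with genes matched by name or by exon records, and 591 with coding records or protein-coding genes only, all moved by -3423 bp. Overlap of same-numbered chromosome IV bins depended on the definition: 438 of 500 pairs overlapped in the coordinates as deposited, 219 by 50% or more and 43 by 90% or more, against 500 with some shared sequence once the after grid was moved back by the gene shift. Of the 13 list members on chromosome IV, 6 changed bin number by midpoint, 5 by the first coding base and 6 by every bin overlapped. An alternative chosen after seeing the data cut the after chromosome into bins of the before width, and 618 genes then changed bin number instead of 280. No paired analysis was possible because the files hold no value for any library, and for that reason other settings for H3pS10 (replicate numbers as a block, another pseudocount, a filter on low bins, leaving out each replicate, input as the reference) were not run. Gene coordinates cannot show substitutions, or insertions and deletions that cancel between neighbouring genes.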

Other observations

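The tests of gene names by arm and of listed genes near the arm intervals were chosen after the coordinates were seen, and the test of left-side genes was set before its result was seen. The intervals between the arms were flanked by convergent genes on 5 nuclear chromosomes, chromosome IV among them, by divergent genes on 2 and by genes in tandem on 9. CDC5, the polo kinase gene, is itself the first right-arm gene of chromosome XIII. On chromosome II, the divergent pair HTA2 and HTB2 lies 1676 and 581 bp from the interval, and the pair HHF1 and HHT1, which encode H4 and H3, lies 16433 and 17391 bp from it on the other side.

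The annotations also list genes that are deleted, wholly or in part, in BY4741 cells. HIS3 (chromosome XV, 721946 to 722608), LEU2 (chromosome III, 91324 to 92418), MET17 (chromosome XII, 732542 to 733876; its older name is MET15) and URA3 (chromosome V, 116167 to 116970) have equal coordinates in both versions, and BY4741 is known to carry full deletions of LEU2, MET17 and URA3 and a partial deletion of HIS3. SGO1, deleted in 1 of the strains, is listed in both versions too.

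All gene movement on chromosome IV started in 1 interval, and a candidate explanation is that the after version lacks the centromere. All 854 chromosome IV genes with an arm in their name lay on the side that a change between the arms predicts, but this count was fixed once RMD1 and NTH1 were known to flank the interval, so it is no evidence for the explanation. The files hold neither sequence nor centromere records. Whether the 625 bp left after still include centromeric DNA, and what fills the 4048 bp before, stays open, as 4048 bp exceeds the interval of all 15 other nuclear chromosomes.

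The change in bin numbers does not come from a shift of the right-side genes alone. Of 268 left-side genes, which did not move, 51 still changed bin number. These changes follow from the narrower after bins (3064 bp against 3071 bp), so they describe the grids and are no independent evidence. With bins of the before width, no left-side gene changed bin number and all 618 right-side genes did, 539 by 1 bin and 79 by 2, so the rescaled grid spreads the difference over both arms. That all 618 changed was fixed in advance, because the shift of 3423 bp is longer than a bin. A comparison of H3pS10 by bin number between the versions would, among bins that do not touch the interval, set sequence up to 2387 bp apart side by side, at bin 149, and the shared sequence is lowest in bin 148 (22.0%), which touches the interval. How the authors compared bins is not given in the sources used here.

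Genes of the fixed lists may lie nearer to the intervals between the arms than other protein-coding genes. Within 20 kb there were 7 of 59 listed genes (11.9%) and 368 of 6605 others (5.57%; two-sided Fisher's exact test, p = 0.0464, Benjamini-Hochberg adjusted p = 0.0742 over 8 tests). The result depended on the window. The same exact test at 30 kb gave 13 of 59 (22.0%) against 543 (8.22%; adjusted p = 0.0074), at 50 kb 17 against 896 (adjusted p = 0.0078) and at 10 kb 4 against 198 (adjusted p = 0.137). With adjacent listed genes counted once, the exact test gave an adjusted p of 0.227 at 10 and 20 kb, 0.0113 at 30 kb and 0.016 at 50 kb. The 6605 other genes were not merged in this way. The windows are nested, so the 8 tests share genes. The 13 genes within 30 kb include CDC5, CDC15, MCD1, RAD61, SMC1, HST2 and 5 histone genes, 4 of them on chromosome II. The lists were picked for mitotic and chromatin functions, the windows were tried after seeing the positions, and genes are not independent replicates, so the pattern stays undecided.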
